A study of Homo sapiens with 4 samples.

How the data were processed

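Nuclear RNA-seq libraries, 4 in number, of HCT116, a human colorectal cancer cell line, were analysed. Per the labels' protocols, cells were treated for 4 h with 30 nM OTS964, an inhibitor given in the series as acting on the kinase CDK11, or with its solvent DMSO, and 2 libraries were made from each treatment. The cytoplasm was removed by lysis in a detergent buffer, RNA was taken from the nuclear pellet, ribosomal RNA was depleted with a RiboCop kit, and libraries that keep the strand were made with a NEBNext Ultra II Directional kit, per the labels' protocols. The nascent RNA, crosslinking and chromatin immunoprecipitation assays that the series design also names were not analysed here.

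The values deposited by the authors were whole-number read counts per Ensembl gene, 1 column per library, with no normalisation and no pooling of replicates. BWA, featureCounts and Subread 1.4.6-p3 are named with genome build GRCh38 per the submitters' processing notes. Which of them aligned the reads, the annotation release, the strand setting of the counting and the treatment of reads with several matches are not given in the sources used here. BWA by itself does not align reads across exon junctions, so if it was the aligner, reads that cross junctions could be lost, and gene-level counts of nuclear RNA hold exonic reads of both spliced and unspliced molecules. The counts therefore do not measure splicing itself. Genes with near-identical copies or many processed pseudogenes (CDK11A and CDK11B, ribosomal proteins, histones, snRNAs, 7SL RNA) may share reads with their copies, and their single values are uncertain.

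The table held 60683 genes and no row without a gene. Symbols were taken from an Ensembl name table (60370 matched) and GENCODE release 29 on GRCh38 (60659 after both). Coordinates, biotypes, gene lengths and intron numbers of the longest transcript came from GENCODE release 29, which held 58496 of the identifiers (96.4%). Total counts per library were between 54433627 and 63256839. With 3 counts taken as the floor, a share of up to 5.51e-06% would go undetected in the library with the lowest total, counting error only, since reads without molecular identifiers are not independent molecules.

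Genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3; glmQLFit with robust estimation and glmQLFTest) on the counts as deposited, with TMM normalisation and genes kept by filterByExpr (minimum count 10, minimum total count 15). This left 21339 genes, which held at least 99.92% of the counts of each library. P-values are two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. A standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. Levels are CPM (counts scaled to a common library size, with the TMM factors), given as mean ± SD of the 2 libraries of a group. The common biological coefficient of variation was 0.121.

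Gene lists were tested with camera (preset correlation 0.01), adjusted over the 32 lists with at least 3 measured members. Camera asks whether a list moved relative to all other genes. An estimated correlation and fry were alternatives, and no camera call of a list or a structure class held with an estimated correlation. The 31 gene lists were replication-dependent and replication-independent histones, the U2 snRNP and branch site, the activated spliceosome, SR proteins and CLK kinases, spliceosomal snRNAs, snoRNAs and scaRNAs, non-coding snoRNA host genes, kinases and factors of transcription elongation, cleavage and polyadenylation, p53 targets, immediate early genes, integrated and ER stress, heat shock, interferon response, NF-kB targets, E2F and S phase, G2/M, homologous recombination and Fanconi genes, the BCL2 and IAP families, ribosomal proteins, ribosome biogenesis, mitochondrially encoded mRNAs, nuclear lncRNAs, RNA polymerase III transcripts with rRNA, known single-exon genes, ZNF zinc finger genes, WNT targets, MAPK feedback genes, cholesterol synthesis, and hypoxia with glycolysis. The 4 marker lists were colorectal epithelium, fibroblast, leukocyte and endothelium. The list of nuclear lncRNAs keeps the name it was given, and where its members lie in the cell was not measured. Coding genes were also grouped by single-exon structure and by quartiles of gene length and intron number, and these classes were tested in the same way.

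The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 6 coding genes with the largest rise and the 6 with the largest fall among those with an adjusted p under 0.05, a mean log2 CPM of at least 3 and group ranges that did not overlap. It also took up to 4 called members of each list with the smallest adjusted p (2 members where none was called), and CDK11A, CDK11B, CCNL1, CCNL2, SF3B1 and PBK. Genes named as the exceptions of a list, as hosts or for their intron annotation were chosen after their values were seen. Some genes that the rule takes are not reported here. The alternatives were relative log expression size factors, total counts without a scaling factor, TMM over coding genes, no filter, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, a test against a 1.5-fold change, the replicate number as a block, and each library left out in turn. Another 2 alternatives were chosen after seeing the data: a scaling that sets the mitochondrially encoded mRNAs to 0, and a fit without small RNA genes.

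The procedure was tested on simulated data drawn from the means and library sizes of this comparison, with 20709 genes tested. Of 50 genes changed at each size, 18 were recovered at 1.5-fold (36%), 39 at 2-fold (78%), and 50 at 4-fold and at 8-fold (100%). Of 20474 unchanged genes, 36 were called. Of 30 lists that shared no member with the simulated list, 2 were called, and of 9 structure classes, 0 were called. The simulation left most genes unchanged (20474 of 20709) and drew each gene independently. In the data 57.7% of genes were called, so the simulated rates need not hold for this comparison. The scaling was not tested under such broad change. Permutation tests of medians used 100000 permutations (10000 for the one within classes of expression) and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. They permuted genes, which are not independent replicates, so their p-values do not measure the spread between libraries.

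The replicates of a group were separate libraries per the labels, which do not say that they came from separate cultures, so the p-values measure only the spread between these libraries, and that spread may be technical. An exact permutation test of single values at 2 against 2 cannot go below p = 0.33, so no such test was made.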

Results

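Nuclear RNA was measured in HCT116 colorectal cancer cells 4 h after 30 nM OTS964 (n = 2 libraries) or DMSO (n = 2). The series is about CDK11, a kinase of the cyclin-dependent family, and its phosphorylation of SF3B1, a subunit of the U2 snRNP that recognises the branch site of introns. The comparison of the inhibitor with its solvent asks which nuclear RNAs changed in this short time. Total counts were 61160166 and 63256839 in DMSO replicates 1 and 2, and 56311030 and 54433627 in OTS964 replicates 1 and 2. Between 29404 and 31823 genes had counts in a library, with the lower numbers in both OTS964 libraries (29404 and 29852).

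The replicates were closer to each other than to the other group. Pearson's r of log2 CPM across genes was 0.993 between the DMSO libraries, 0.989 between the OTS964 libraries and 0.952 to 0.958 between groups; genes are not independent replicates. The replicates were not copies of one library, since their counts differed by more than sampling noise (chi-square per degree of freedom 14.4 in DMSO and 29.6 in OTS964).

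The make-up of the RNA from the nuclear pellets differed between the groups. The mRNAs encoded by the mitochondrial genome held 0.824% ± 0.0613 of counts in DMSO and 1.13% ± 0.0944 in OTS964 (SD, n = 2 each). Ribosomal protein genes held 3.64% ± 0.0346 and 5.11% ± 0.144, and RN7SL1, the RNA of the signal recognition particle, 3.15% ± 0.335 and 4.8% ± 0.0918. MALAT1, a lncRNA of nuclear speckles, held 0.288% ± 0.0399 in DMSO and 0.187% ± 0.0265 in OTS964. NEAT1, the lncRNA on which paraspeckles form, held 0.0205% ± 0.00273 and 0.00937% ± 0.000632. In each of these 5 cases the libraries of the groups did not overlap. The share of SNORD3A, the U3 small nucleolar RNA, lay apart in both OTS964 libraries (1.44% and 0.608%), around the DMSO values of 1.002% and 0.940%. Its log2 fold change was 0.39 (adjusted p = 0.634) and passed the test in opposite directions without OTS964 replicate 1 (-0.40) and without OTS964 replicate 2 (0.91). Coding genes held 90.3% ± 0.167 in DMSO and 87.7% ± 0.0594 in OTS964, and the 10 highest genes 7.49% ± 0.311 and 9.83% ± 0.704. No test was made of these shares, since an exact permutation test of 2 against 2 libraries cannot go below p = 0.33. More cytoplasm or mitochondria carried over into both OTS964 preparations cannot be told apart from a change of nuclear RNA, since it is confounded with the group.

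Genes changed in both directions with OTS964. Of 21339 genes, 5710 rose and 6611 fell, while 9018 did not pass the test. Changes of at least 2-fold were more often falls, with 1517 called genes up and 3362 down. Among 13263 protein-coding genes, 3844 rose and 4524 fell, and by at least 2-fold 265 rose and 1631 fell. Group ranges did not overlap in 80.4% of genes, against 33.3% by chance. The split of calls depended on the scaling and the tool: 46.3% of calls were rises with TMM, and 22.6% with total counts alone (2839 rose and 9730 fell), which shifted the median log2 fold change of all genes by -0.30. DESeq2 called 5461 rises and 4983 falls, so that 52.3% of its calls were rises. Without DMSO replicate 1, 3659 of 21939 genes rose and 4485 fell, without DMSO replicate 2, 3739 of 22128 rose and 4577 fell, and without a filter 5526 of 36732 rose and 7913 fell. Setting the mitochondrially encoded mRNAs to 0, a scaling chosen after seeing the data, shifted the median by -0.73 and gave 911 rises and 14927 falls. All changes below are relative to the TMM scaling. They also followed expression: in the highest expression quartile of coding genes 2040 of 3316 rose and 466 fell (median 0.30). In the lowest, 211 of 3316 rose and 1333 fell (median -0.52). Of the gene lists below, only the immediate early genes were compared with genes of like expression.

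**Figure D1:**
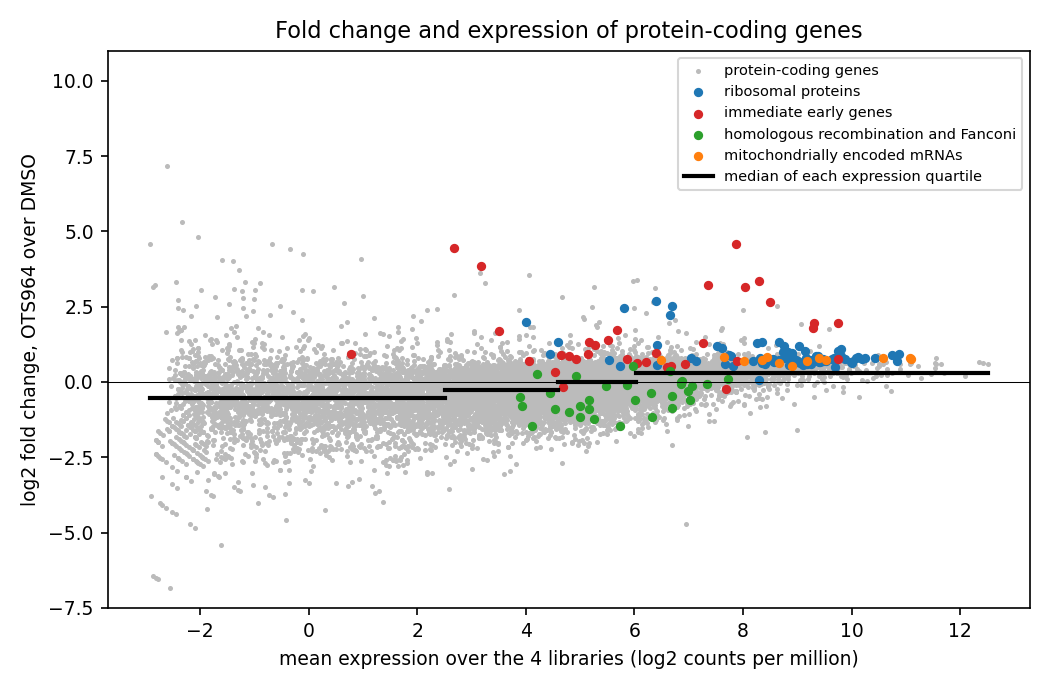
Log2 fold change (OTS964 over DMSO) against mean expression (log2 CPM over the 4 libraries) for the 13263 coding genes (grey), with ribosomal protein, immediate early, homologous recombination and Fanconi, and mitochondrially encoded genes in colour and the median of each expression quartile as a black line. The medians were -0.52, -0.28, -0.01 and 0.30 from the lowest to the highest quartile with TMM scaling, while total counts alone shifted the median of all genes by -0.30.

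The kinase named by the series and its partners rose in most cases. CDK11B, 1 of a pair of near-identical CDK11 genes, rose from 33.5 ± 1.89 to 65.7 ± 10.5 CPM (SD, n = 2 each; log2 fold change 0.97, SE 0.11, adjusted p = 0.000404). CDK11A rose from 3.10 ± 0.521 to 9.24 ± 0.883 CPM (1.58, SE 0.16, adjusted p = 0.000125), and reads of both copies may be shared. CCNL1, which encodes cyclin L1, a partner of CDK11, rose from 117.4 ± 1.46 to 670.7 ± 50.4 CPM (2.51, SE 0.07, adjusted p = 1.10e-06). CCNL2, the gene of cyclin L2, did not pass the test (0.13, SE 0.10, adjusted p = 0.301), though without OTS964 replicate 2 it did (0.28, adjusted p = 0.00181). SF3B1 rose from 542.5 ± 4.61 to 801.3 ± 32.8 CPM (0.56, SE 0.06, adjusted p = 0.000142). PBK, the gene of a mitotic kinase for which OTS964 was first described as an inhibitor, rose from 83.8 ± 0.699 to 117.6 ± 2.81 CPM (0.49, SE 0.06, adjusted p = 0.000286). The log2 fold changes of SF3B1 and PBK were below the shift of the scaling that sets the mitochondrially encoded mRNAs to 0, and change sign with it. On GRCh38, CDK11A (ENSG00000008128) lies on chromosome 1 from 1702730 to 1724324, CDK11B (ENSG00000248333) on chromosome 1 from 1635227 to 1659012, and CCNL2 (ENSG00000221978) on chromosome 1 from 1385711 to 1399328. CCNL1 (ENSG00000163660) lies on chromosome 3 from 157146508 to 157160760, SF3B1 (ENSG00000115524) on chromosome 2 from 197389784 to 197435091 and PBK (ENSG00000168078) on chromosome 8 from 27809620 to 27838095. Counts were of exons of whole genes. The inhibitor acts on the protein, so these RNA levels do not check the labels.

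**Figure D2:**
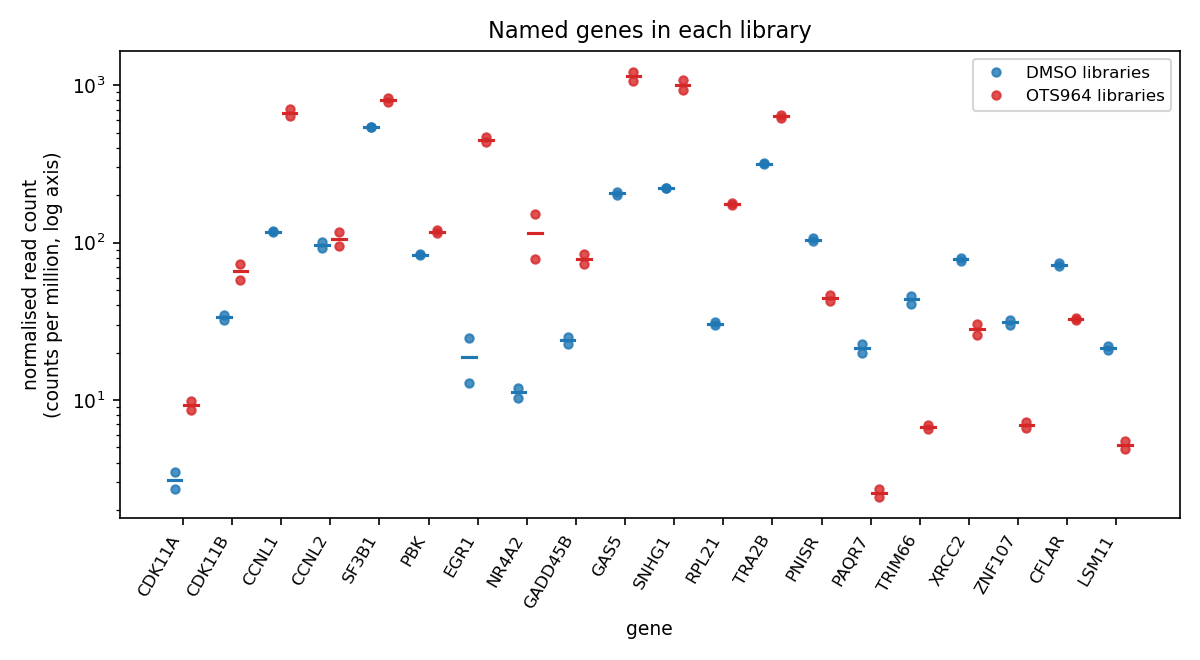
Normalised read counts (CPM, log axis) of named genes in each DMSO (blue) and OTS964 (red) library, with the mean of each group as a bar. CCNL1 rose from a mean of 117.4 to 670.7 CPM and PAQR7 fell from 21.3 to 2.58 CPM, while the libraries of CCNL2 overlapped between groups.

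The 6 largest rises taken by the rule included 3 transcription factor genes. EGR1 (ENSG00000120738), a zinc finger transcription factor of the immediate early response, rose from 18.8 ± 8.48 to 450.1 ± 24.5 CPM (4.58, SE 0.48, adjusted p = 0.0131), and its relative EGR3 from 1.18 ± 0.271 to 17.2 ± 4.23 CPM (3.86, SE 0.24, adjusted p = 5.01e-05). NR4A2, an orphan nuclear receptor gene, rose from 11.2 ± 1.16 to 115.4 ± 52.5 CPM (3.37, SE 0.49, adjusted p = 0.0226). The aminopeptidase gene LVRN (3.62, SE 0.26, adjusted p = 0.000123), the oviductal glycoprotein gene OVGP1 (3.54, SE 0.16, adjusted p = 1.32e-05) and NUAK2, the gene of an AMPK-related kinase (3.37, SE 0.23, adjusted p = 0.000652), also rose. The largest falls were of PAQR7, a membrane progestin receptor gene, from 21.3 ± 2.10 to 2.58 ± 0.226 CPM (-3.05, SE 0.13, adjusted p = 4.30e-06), and OSGIN1, a gene induced by oxidative stress (-2.95, SE 0.26, adjusted p = 0.000606). The transcription factor gene SP6 (-2.74, SE 0.11), TRIM66 (-2.69, SE 0.10), RSKR (-2.60, SE 0.24) and the deubiquitinase gene USP49 (-2.57, SE 0.17) fell as well, with adjusted p of 3.85e-06, 2.57e-06, 0.000307 and 2.08e-05. The calls of EGR1 were lost without OTS964 replicate 1 (adjusted p = 0.122) or replicate 2 (0.128) and with the replicate number as a block (0.0876). Those of NR4A2 were lost without DMSO replicate 1 (0.135) or replicate 2 (0.126), without a filter (0.0558) and with the block (0.130), those of OSGIN1 without OTS964 replicate 1 (0.0594) or replicate 2 (0.0767) and that of RSKR without OTS964 replicate 2 (0.0538), all in the same direction.

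Genes of the splicing machinery rose together. So did most coding genes of the highest expression quartile (2040 of 3316 rose, 466 fell, median 0.30), and the lists here were not matched on expression. Of the 25 measured genes of the U2 snRNP and branch site, 24 rose and 0 fell (24 and 0 adjusted over the list alone), with a median log2 fold change of 0.52 that was -0.22 with the mitochondrially encoded mRNAs set to 0. DHX15, the helicase that takes apart spliceosomes, rose by 0.73 (SE 0.06, adjusted p = 3.85e-05), and SNRPA1, which encodes a U2-specific protein, by 0.80 (SE 0.07, adjusted p = 5.66e-05). DDX42, a helicase gene, was the single member that did not pass (0.03, adjusted p = 0.76), and with total counts it passed at -0.28 (adjusted p = 0.00399). Of 32 genes of the activated spliceosome, 27 rose and 1 fell (29 and 1 adjusted over the list alone), with a median of 0.35 that was 0.04 with total counts and -0.39 with the mitochondrially encoded mRNAs set to 0. SYF2 (0.79, SE 0.07, adjusted p = 6.08e-05) and PRPF19, the ubiquitin ligase of the Prp19 complex (0.50, SE 0.06, adjusted p = 0.000194), were among those that rose, and BUD13 fell by 0.62 on the log2 scale (adjusted p = 0.000429). The mitochondrially encoded mRNAs, given beside these lists as a measured fact, had a median of 0.74. With total counts 13 of the U2 list rose and 1 fell (median 0.21), and 8 of the activated spliceosome rose and 4 fell; with the mitochondrially encoded mRNAs set to 0 these counts were 0 and 16, and 0 and 26. The camera adjusted p was 1.39e-08 for the U2 list and 5.06e-06 for the activated spliceosome, and adjusted p = 0.456 and adjusted p = 0.525 with an estimated correlation.

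Regulators of splice site choice moved in both directions. Of 30 SR protein and CLK kinase genes, 19 rose and 5 fell (19 and 5 adjusted over the list alone), with a median of 0.35 that was 0.04 with total counts and -0.39 with the mitochondrially encoded mRNAs set to 0. TRA2B rose from 316.3 ± 2.74 to 634.2 ± 22.1 CPM (SE of the log2 fold change 0.06, adjusted p = 1.26e-05), the splicing coactivator gene SRRM1 rose by 0.96 (SE 0.06, adjusted p = 1.32e-05) and CLK1, the gene of a kinase of SR proteins, by 1.15 (SE 0.09, adjusted p = 5.55e-05). PNISR, which encodes an arginine-serine-rich protein, fell from 104.1 ± 2.92 to 44.7 ± 2.93 CPM (-1.22, SE 0.07, adjusted p = 1.30e-05). LUC7L3, SRSF5, SRPK2 and DDX5 were the other members that fell. The DDX5 call was lost without DMSO replicate 2 (adjusted p = 0.0725) or OTS964 replicate 2 (0.192), with relative log expression size factors (0.124), with the replicate number as a block (0.0562) and with DESeq2 (0.113). With total counts 13 rose and 10 fell. The camera adjusted p was 0.000455, and adjusted p = 0.528 with an estimated correlation. Of 15 measured spliceosomal snRNA genes, 8 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 1.14, camera adjusted p = 0.00945 and adjusted p = 0.525 with an estimated correlation. RNU6-2 rose by 1.03 (SE 0.19, adjusted p = 0.00199) and RNU4-2 by 1.26 (SE 0.29, adjusted p = 0.0242), and both have near-identical copies. The snRNA call was lost without DMSO replicate 1 (adjusted p = 0.724) and without OTS964 replicate 2 (0.0565), and the RNU4-2 call without DMSO replicate 1 (0.119) or replicate 2 (0.134), with total counts (0.0545), without a filter (0.178) and with the block (0.189). With total counts 3 of the 15 rose, and with the mitochondrially encoded mRNAs set to 0 none passed the test. The snRNA list held 0.00945% ± 0.00657 of counts in DMSO and 0.00728% ± 0.00116 in OTS964. U2 genes and their copies held 166.1 and 178.3 CPM (scaled by total counts alone) in DMSO replicates 1 and 2, and 9.9 and 306.6 in OTS964 replicates 1 and 2.

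Small nucleolar RNA genes and the non-coding genes that carry them in their introns rose in most cases. Reads of unspliced host RNA may count toward snoRNA genes that lie in introns, so these counts need not be of the snoRNAs alone. Of 153 measured snoRNAs and scaRNAs, which guide the modification of rRNA and snRNA, 123 rose and 0 fell (124 and 0 adjusted over the list alone), with a median of 1.57, camera adjusted p = 5.08e-27 and adjusted p = 0.358 with an estimated correlation. SNORD46 rose from 3.03 ± 0.217 to 26.3 ± 2.04 CPM (3.12, SE 0.11, adjusted p = 2.57e-06) and SNORD6 from 1.65 ± 0.266 to 17.7 ± 1.59 CPM (3.42, SE 0.15, adjusted p = 5.25e-06). Of 23 non-coding host genes, 15 rose and 3 fell (15 and 3 adjusted over the list alone), with a median of 0.81, camera adjusted p = 2.67e-07 and adjusted p = 0.456 with an estimated correlation. GAS5 rose from 206.1 ± 6.22 to 1142 ± 100.2 CPM (2.47, SE 0.08, adjusted p = 1.57e-06), SNHG1 from 222.1 ± 1.44 to 1008 ± 104.4 CPM (2.18, SE 0.08, adjusted p = 2.77e-06) and ZFAS1 from 73.8 ± 0.508 to 293.3 ± 8.85 CPM (1.99, SE 0.06, adjusted p = 1.38e-06). SNHG3 rose by 1.76 (SE 0.06, adjusted p = 2.00e-06). The hosts SNHG20, SNHG4 and EPB41L4A-AS1 fell. The last call was lost without DMSO replicate 1 (adjusted p = 0.0807), DMSO replicate 2 (0.117) or OTS964 replicate 2 (0.0759), with relative log expression size factors (0.0761), with TMM over coding genes (0.0536) and with DESeq2 (0.123). The medians of both lists stayed above 0 under each scaling tried, with the lowest at 0.85 and 0.07 where the mitochondrially encoded mRNAs were set to 0; there 84 snoRNAs and scaRNAs rose and 8 fell, and 9 hosts rose and 8 fell.

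Ribosomal protein, mitochondrial and RNA polymerase III transcripts rose. Of 82 ribosomal protein genes, 80 rose and 0 fell (80 and 0 adjusted over the list alone), with a median of 0.77, and 0.04 with the mitochondrially encoded mRNAs set to 0. RPL21 (2.53, SE 0.07, adjusted p = 9.02e-07), RPS26 (2.47, SE 0.09, adjusted p = 2.57e-06) and RPL17 (2.23, SE 0.07, adjusted p = 2.00e-06) were among those that rose; each has processed pseudogenes that may share its reads. Of 30 ribosome biogenesis genes, 22 rose and 2 fell (23 and 2 adjusted over the list alone), with a median of 0.36 that was 0.06 with total counts and -0.38 with the mitochondrially encoded mRNAs set to 0. UTP3, a gene of the small subunit processome, rose by 1.04 (SE 0.07, adjusted p = 1.78e-05) and NPM1, which encodes nucleophosmin, by 0.66 (SE 0.06, adjusted p = 6.21e-05), while POLR1A and RRP12 fell. The RRP12 call was lost without DMSO replicate 1 (adjusted p = 0.0614), DMSO replicate 2 (0.0706) or OTS964 replicate 2 (0.0716). The 13 mRNAs encoded in mitochondria, which are neither made by RNA polymerase II nor spliced, rose without exception (13 and 0 adjusted over the list alone), with a median of 0.74 (0.43 with total counts). MT-CO1 rose by 0.75 (SE 0.07, adjusted p = 8.78e-05) and MT-ATP6 by 0.71 (SE 0.06, adjusted p = 4.56e-05). Of 7 measured RNA polymerase III and rRNA genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 1.20. The nuclear rRNA genes named in this list were not found by symbol, so it measured no nuclear rRNA. Its only rRNA genes are those of the mitochondrial genome, and rRNA was depleted from the libraries. BCYRN1, a small cytoplasmic RNA gene, rose by 1.43 (SE 0.07, adjusted p = 8.59e-06) and RN7SL1 by 0.91 (SE 0.10, adjusted p = 0.000158). With total counts 78 ribosomal protein genes rose and 1 fell (median 0.47), and 11 biogenesis genes rose and 7 fell. With the mitochondrially encoded mRNAs set to 0, the counts were 20 and 4, and 1 and 24, and 2 RNA polymerase III and rRNA genes rose. The camera adjusted p of these 4 lists was 6.51e-35, 3.13e-05, 8.78e-08 and 0.000325, and with an estimated correlation adjusted p = 0.456, adjusted p = 0.528, adjusted p = 0.456 and adjusted p = 0.421.

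Genes of the immediate early and heat shock responses rose. Of 34 immediate early genes, which respond first to growth factors and stress, 29 rose and 1 fell (30 and 1 adjusted over the list alone), with a median of 0.96, and 0.22 with the mitochondrially encoded mRNAs set to 0. GADD45B rose from 23.9 ± 1.64 to 78.6 ± 8.38 CPM (1.72, SE 0.09, adjusted p = 1.11e-05), IER3 from 260.9 ± 2.42 to 1013 ± 157.2 CPM (1.96, SE 0.11, adjusted p = 2.55e-05) and EGR2 from 0.565 ± 0.0687 to 12.4 ± 3.77 CPM (4.45, SE 0.27, adjusted p = 2.97e-05). MCL1, an inhibitor of apoptosis with a short-lived mRNA, was the member that fell (-0.23, adjusted p = 0.0166). Its call was lost without DMSO replicate 1 (0.0598) or OTS964 replicate 2 (0.0523). Of 16 heat shock genes, 15 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 0.61 that was -0.13 with the mitochondrially encoded mRNAs set to 0. HSPH1, a chaperone gene of the HSP110 family, rose by 1.02 (SE 0.06, adjusted p = 1.32e-05) and CHORDC1, a gene of an HSP90 partner, by 0.88 (SE 0.06, adjusted p = 2.29e-05). The mitochondrially encoded mRNAs had a median of 0.74 on the same scale. With those set to 0, 15 immediate early genes rose and 4 fell, and 1 heat shock gene rose and 3 fell. With total counts 27 rose and 2 fell, and 11 rose and 0 fell. The camera adjusted p was 2.07e-14 and 3.19e-07, and adjusted p = 0.421 for both lists with an estimated correlation.

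**Figure D3:**
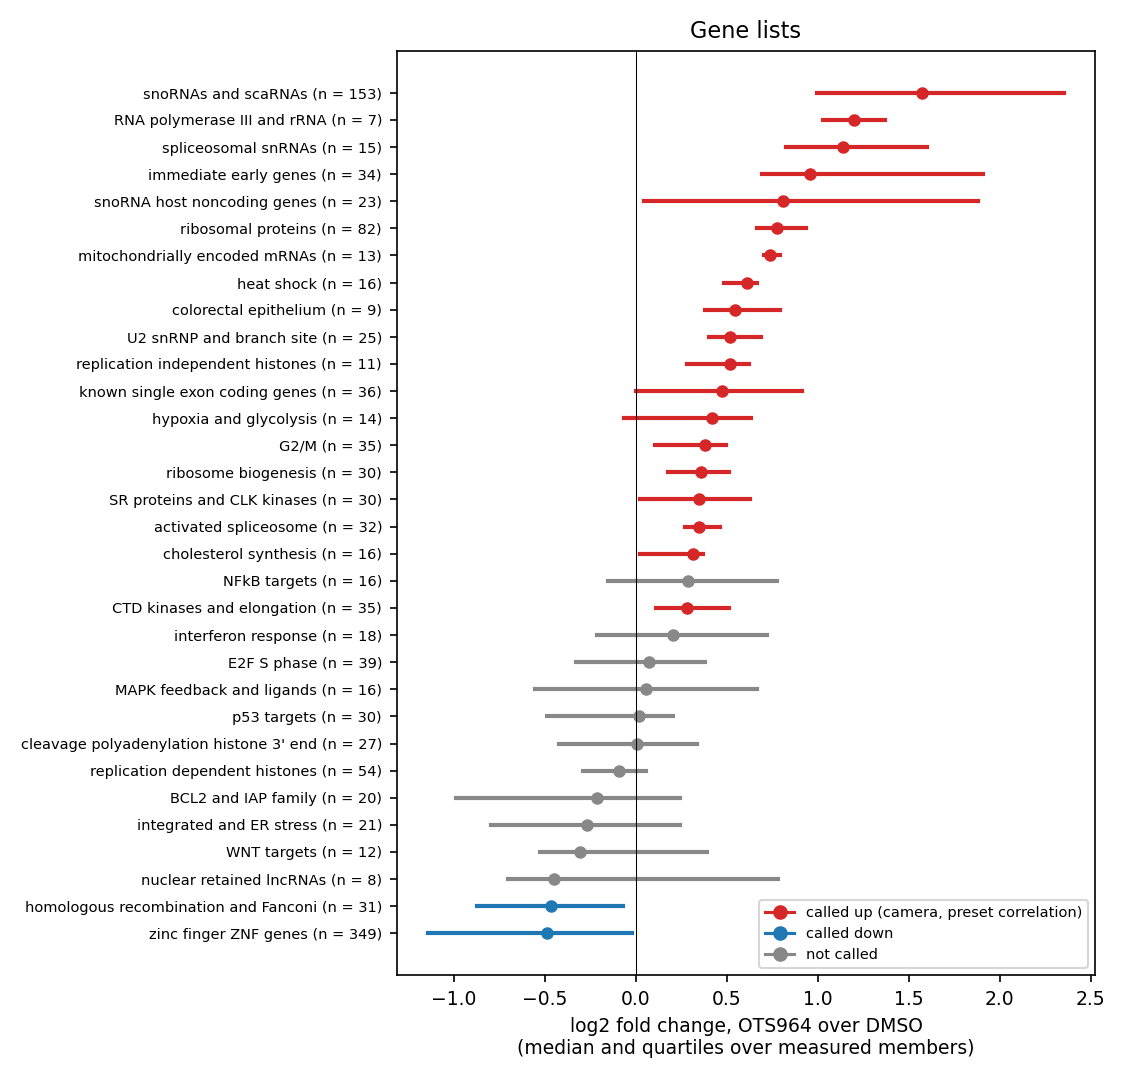
Median and quartiles of the log2 fold change (OTS964 over DMSO) over the measured members of each gene list with at least 3 measured members, in red or blue where camera called the list up or down with its preset correlation and in grey where it did not; no call held with an estimated correlation. Medians ran from -0.49 for ZNF genes to 1.57 for snoRNAs and scaRNAs with TMM scaling; those of the elongation, NF-kB, interferon, E2F, MAPK, p53 and cleavage lists fell below 0 with total counts, and of the lists above 0 only the snoRNA, snoRNA host, snRNA, RNA polymerase III, immediate early and ribosomal protein lists stayed there with the mitochondrially encoded mRNAs set to 0, which puts those mRNAs themselves at 0.

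Genes of homologous recombination and of zinc finger proteins fell. In the lowest expression quartile of coding genes the median was -0.52, and the lists here were not matched on expression. Of 31 homologous recombination and Fanconi genes, which repair breaks and crosslinks of DNA, 19 fell and 2 rose (19 and 4 adjusted over the list alone), with a median of -0.47 that kept its sign under each scaling. XRCC2 fell from 78.2 ± 2.59 to 28.2 ± 3.44 CPM (-1.47, SE 0.09, adjusted p = 1.78e-05). BRIP1, a helicase gene, fell from 109.9 ± 8.15 to 49.5 ± 1.97 CPM (-1.15, SE 0.08, adjusted p = 1.92e-05), PALB2, the gene of the partner of BRCA2, by 1.15 on the log2 scale (SE 0.09, adjusted p = 2.96e-05) and XRCC3 by 1.24 (SE 0.09, adjusted p = 3.23e-05). RAD51C and CHEK1 were the members that rose. CHEK1 did not pass with total counts (adjusted p = 0.368). Of 349 ZNF genes, most of which encode zinc finger transcription factors, 207 fell and 42 rose (the same counts adjusted over the list alone), with a median of -0.49 that kept its sign under each scaling. ZNF8 (-2.44, SE 0.11, adjusted p = 5.36e-06), ZNF107 (-2.16, SE 0.10, adjusted p = 5.03e-06) and ZNF740 (-1.94, SE 0.09, adjusted p = 5.25e-06) fell, while ZNF410 rose from 6.31 ± 1.04 to 44.8 ± 0.532 CPM (2.83, SE 0.12, adjusted p = 5.50e-06). With total counts 1 recombination gene rose and 27 fell (median -0.77), and 24 ZNF genes rose and 258 fell (median -0.79). The camera adjusted p was 0.000311 and 9.99e-08, and adjusted p = 0.528 and adjusted p = 0.525 with an estimated correlation.

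The BCL2 and IAP families and the p53 targets held more falls than rises among their called members. Of 20 BCL2 and IAP family genes, which regulate apoptosis, 11 fell and 6 rose (11 and 6 adjusted over the list alone), with a median of -0.22 and a camera adjusted p of 0.0795, so the list was not called. CFLAR, an inhibitor of caspase 8, fell from 72.4 ± 2.04 to 32.8 ± 0.615 CPM (-1.14, SE 0.07, adjusted p = 1.35e-05), and BCL2L2 (-1.34, SE 0.08, adjusted p = 1.68e-05), BAK1 (-1.70, SE 0.12, adjusted p = 2.43e-05) and BIK (-1.88, SE 0.14, adjusted p = 3.48e-05) fell too; CFLAR and BCL2L2 oppose and BAK1 and BIK promote apoptosis. The list passed without DMSO replicate 1 (adjusted p = 0.0214), DMSO replicate 2 (0.0241) or OTS964 replicate 1 (0.0483), and with total counts (0.0340), where 0 rose and 12 fell with a median of -0.52. Of 30 p53 targets, 12 fell and 6 rose (12 and 6 adjusted over the list alone); the median was 0.01 (-0.29 with total counts, where 1 rose and 17 fell; -0.08 to 0.06 with 1 library left out), the mean -0.21 and the direction of the test down, with camera adjusted p = 0.358. AEN, a nuclease gene, fell by 1.78 on the log2 scale (SE 0.13, adjusted p = 0.000124) and SESN1, a stress-induced gene, by 1.57 (SE 0.14, adjusted p = 6.18e-05). Of 27 cleavage and polyadenylation genes, 9 rose and 9 fell (9 and 9 adjusted over the list alone), with a median of 0.00 (-0.30 with total counts, where 5 rose and 15 fell; -0.04 to 0.09 with 1 library left out), a mean of -0.14 and camera adjusted p = 0.857. LSM11, a subunit of the U7 snRNP that forms the 3' ends of histone mRNAs, fell from 21.4 ± 1.02 to 5.20 ± 0.451 CPM (-2.04, SE 0.11, adjusted p = 8.59e-06), and RBBP6 (-1.20, SE 0.06, adjusted p = 8.57e-06) and CPSF4 (-1.20, SE 0.08, adjusted p = 1.99e-05) also fell.

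Histone genes were tested as 2 lists, without a test of the difference between them. Of 54 measured replication-dependent histone genes, whose mRNAs lack introns and poly(A) tails, 2 rose and 10 fell (1 and 8 adjusted over the list alone), with a median of -0.09. With total counts 1 rose and 37 fell (median -0.39), and with the mitochondrially encoded mRNAs set to 0, 0 rose and 47 fell (median -0.83). The median ranged from -0.14 to -0.02 with 1 library left out. H3C1 fell from 67.8 ± 3.95 to 43.6 ± 2.71 CPM (-0.64, SE 0.08, adjusted p = 0.000267), and H4C3 rose from 355.8 ± 19.4 to 493.4 ± 9.89 CPM (0.47, SE 0.06, adjusted p = 0.000397). H2AC15 was the other member that rose (0.20, adjusted p = 0.0257). With total counts H2AC15 lay at -0.11 and did not pass. Its call was also lost without DMSO replicate 1 (0.158) or replicate 2 (0.135) and without a filter (0.142). The camera adjusted p was 0.472, and 0.0382 with total counts. Of 11 replication-independent histone genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.52 that was 0.21 with total counts (5 rose, 2 fell) and -0.22 with the mitochondrially encoded mRNAs set to 0 (1 rose, 6 fell), camera adjusted p = 0.0027 and adjusted p = 0.421 with an estimated correlation. CENPA, the histone H3 variant gene of centromeres, fell from 22.5 ± 1.26 to 12.9 ± 0.659 CPM (-0.80, SE 0.09, adjusted p = 0.000189).

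Among genes of transcription elongation and of the cell cycle, more members rose than fell with TMM scaling. Of 35 kinases and factors of elongation, 20 rose and 5 fell (20 and 5 adjusted over the list alone), with a median of 0.28 that was -0.02 with total counts (11 rose, 9 fell) and -0.46 with the mitochondrially encoded mRNAs set to 0 (4 rose, 28 fell), camera adjusted p = 0.000444 and adjusted p = 0.485 with an estimated correlation. SUPT6H, the gene of an elongation factor, rose by 0.54 (SE 0.06, adjusted p = 0.000163), beside CCNL1 and CDK11A. NELFA, CDK8, AFF4, CDK13 and CDK12 were the members that fell. The CDK12 call was lost without OTS964 replicate 2 (adjusted p = 0.0699). Of 35 G2/M genes, 24 rose and 4 fell (24 and 4 adjusted over the list alone), with a median of 0.38 that was 0.08 with total counts (13 rose, 10 fell) and -0.35 with the mitochondrially encoded mRNAs set to 0 (0 rose, 28 fell), camera adjusted p = 0.000152 and adjusted p = 0.525 with an estimated correlation. MKI67, the proliferation marker, rose by 0.64 (SE 0.06, adjusted p = 8.60e-05), while KIF2C, a mitotic kinesin gene, fell by 0.97 (SE 0.07, adjusted p = 2.52e-05), as did NDC80, BIRC5 and CCNF. The calls of BIRC5 were lost without DMSO replicate 1 (0.0527) or OTS964 replicate 2 (0.0595), with relative log expression size factors (0.0565) and with DESeq2 (0.0569). Those of CCNF were lost without DMSO replicate 1 (0.0918) or replicate 2 (0.0545) and without a filter (0.0862). Of 39 E2F and S phase genes, 18 rose and 14 fell (19 and 14 adjusted over the list alone); the median was 0.07 (0.03 to 0.13 with 1 library left out; -0.23 with total counts, where 4 rose and 21 fell), the mean -0.02 and the direction of the test up, with camera adjusted p = 0.406. With the mitochondrially encoded mRNAs set to 0, 0 rose and 38 fell. TK1, thymidine kinase, rose by 0.54 (SE 0.06, adjusted p = 0.000144), and GINS3, a gene of the replicative helicase, fell by 0.87 (SE 0.09, adjusted p = 0.000129).

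Stress and signalling lists were mixed. Of 21 integrated and ER stress genes, 2 rose and 7 fell (2 and 6 adjusted over the list alone), with a median of -0.27 and camera adjusted p = 0.218. The median was -0.48 to -0.17 with 1 library left out and -0.57 with total counts, where 1 rose and 10 fell. ATF4, the transcription factor of this response, fell from 377.5 ± 36.4 to 185.5 ± 19.1 CPM (SE 0.10, adjusted p = 0.000145), while the chaperone gene HSPA5 rose by 0.51 (SE 0.07, adjusted p = 0.000567), as did SHMT2, though not with total counts (adjusted p = 0.142). This list passed without DMSO replicate 2 (adjusted p = 0.00357) and without OTS964 replicate 1 (0.0182). Of 16 NF-kB targets, 7 rose and 3 fell (7 and 3 adjusted over the list alone), with a median of 0.29 that was -0.02 with total counts (4 rose, 4 fell), and camera adjusted p = 0.0988, or 0.00216 without OTS964 replicate 1. NFKBIA, the inhibitor gene of the pathway, rose by 1.24 (SE 0.10, adjusted p = 5.90e-05), and RELB (-1.13, SE 0.12, adjusted p = 0.000125), NFKB2 and TRAF1 fell. The TRAF1 call was lost without DMSO replicate 1 (0.241), DMSO replicate 2 (0.0583) or OTS964 replicate 1 (0.0568) and with DESeq2 (0.179). Of 18 interferon response genes, 6 rose and 2 fell (6 and 2 adjusted over the list alone), with a median of 0.20 that was -0.10 with total counts (1 rose, 4 fell) and 0.09 to 0.29 with 1 library left out, and camera adjusted p = 0.23. IRF1 rose by 0.97 (SE 0.10, adjusted p = 0.000102), and MX1 fell, though not without DMSO replicate 1 (0.0513) or replicate 2 (0.188), nor with DESeq2 (0.153). Of 16 MAPK feedback genes and ligands, 6 rose and 6 fell (6 and 6 adjusted over the list alone), with a median of 0.05 that was -0.25 with total counts (5 rose, 8 fell) and 0.02 to 0.12 with 1 library left out, and camera adjusted p = 0.472. The feedback genes SPRY2 (1.54, SE 0.10, adjusted p = 1.69e-05) and DUSP6 (1.402, SE 0.09, adjusted p = 2.29e-05) rose, and SPRED2 fell by 0.81 on the log2 scale (SE 0.08, adjusted p = 8.32e-05). Of 12 measured WNT targets, 3 rose and 3 fell (3 and 3 adjusted over the list alone), with a median of -0.31 (-0.61 with total counts, where 2 rose and 5 fell) and camera adjusted p = 0.964. AXIN2 rose from 6.37 ± 0.215 to 12.7 ± 2.70 CPM (SE 0.16, adjusted p = 0.00104) and EPHB3, an ephrin receptor gene, fell by 1.83 on the log2 scale (SE 0.23, adjusted p = 0.000294). TCF7 and NOTUM rose too, and ZNRF3 and DKK1 fell. The NOTUM call was lost without DMSO replicate 1 (0.103) and with total counts (0.0610), and that of DKK1 without DMSO replicate 2 (0.0760), OTS964 replicate 1 (0.387) or OTS964 replicate 2 (0.290), with TMM over coding genes (0.0687) and without a filter (0.201).

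Metabolic genes, a list of known single-exon genes and epithelial markers rose on balance with TMM scaling, and their medians were below 0 with the mitochondrially encoded mRNAs set to 0. Of 16 cholesterol synthesis genes, 6 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.31 (-0.42 with those mRNAs at 0), camera adjusted p = 0.0406 and adjusted p = 0.741 with an estimated correlation. FDPS rose by 0.41 (SE 0.07, adjusted p = 0.0011) and MSMO1 by 0.67 (SE 0.12, adjusted p = 0.00239), both genes of enzymes of this pathway, and neither passed with total counts (0.170 and 0.0515). The call of this list was lost without DMSO replicate 1 (0.251), without OTS964 replicate 2 (0.172), with total counts (0.123) and with the CPM filter (0.0937). The median of the list ranged from 0.10 to 0.42 with 1 library left out and was 0.01 with total counts, where 1 rose and 3 fell. Of 14 hypoxia and glycolysis genes, 9 rose and 3 fell (9 and 3 adjusted over the list alone), with a median of 0.42 (0.12 with total counts, where 7 rose and 5 fell, and -0.31 with those mRNAs at 0), camera adjusted p = 0.0281 and adjusted p = 0.528 with an estimated correlation. LDHA (0.69, SE 0.07, adjusted p = 8.78e-05) and ENO1 (0.63, SE 0.07, adjusted p = 0.000126), both of glycolysis, rose, and PDK1, ANKRD37 and EGLN3, all targets of hypoxia, fell. The EGLN3 call was lost without DMSO replicate 1 (0.0846) or replicate 2 (0.0943) and with DESeq2 (0.0570). The call of the list was lost without OTS964 replicate 1 (0.100) and with total counts (0.0692). Of 36 known single-exon coding genes, 19 rose and 5 fell (19 and 6 adjusted over the list alone), with a median of 0.47 (0.17 with total counts, where 14 rose and 9 fell, and -0.26 with those mRNAs at 0), camera adjusted p = 0.00045 and adjusted p = 0.421 with an estimated correlation. This list shares JUN, JUNB, JUND, IER2 and IER5 with the immediate early genes, and HSPA1A and HSPA1B with the heat shock genes. Its call is therefore not independent of theirs. IER5L (1.17, SE 0.07, adjusted p = 1.69e-05) and PURB (1.16, SE 0.07, adjusted p = 1.70e-05) rose, and CEBPA, PURA, ZXDA, CLDN4 and CITED4 fell. Without DMSO replicate 1 the calls of ZXDA (0.0759), CLDN4 (0.101) and CITED4 (0.136) were lost. Without DMSO replicate 2 those of CLDN4 (0.169) and CITED4 (0.224) were. That of CITED4 was also lost without OTS964 replicate 1 (0.124) and with DESeq2 (0.267), and that of CLDN4 with TMM over coding genes (0.0621) and without a filter (0.121). Of 9 measured colorectal epithelium markers, 7 rose and 2 fell (7 and 2 adjusted over the list alone), with a median of 0.55 (0.24 with total counts, where 4 rose and 2 fell, and -0.19 with those mRNAs at 0), camera adjusted p = 0.013 and adjusted p = 0.456 with an estimated correlation. The keratin genes KRT18 (0.84, SE 0.08, adjusted p = 6.68e-05) and KRT8 (0.79, SE 0.08, adjusted p = 9.02e-05) rose, and the transcription factor genes ELF3 and CDX2 fell. These calls were lost without DMSO replicate 2 (0.111 and 0.0540) and for CDX2 also without DMSO replicate 1 (0.0842). Of the markers of other cell types, 1 of 8 fibroblast genes was measured (COL1A1, -0.18, SE 0.18, adjusted p = 0.405, and 0.0465 with total counts), 1 of 8 leukocyte genes (CD14, 0.0794 ± 0.0502 CPM in DMSO and 0.261 ± 0.0271 in OTS964, adjusted p = 0.0265) and 1 of 5 endothelium genes (VWF, -0.25, SE 0.36, adjusted p = 0.559), so these 3 lists were not tested. The CD14 call was lost without DMSO replicate 1 (0.255), DMSO replicate 2 (0.0705) or OTS964 replicate 2 (0.0788), with total counts (0.0602) and with DESeq2 (0.184).

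The lncRNAs of the list named nuclear moved apart, and where each of them lies in the cell was not measured here. Of 8, 3 rose and 5 fell (3 and 5 adjusted over the list alone); the median was -0.45 (-0.75 with total counts), the mean -0.11 and the direction of the test down, with camera adjusted p = 0.964. NORAD (0.80, SE 0.06, adjusted p = 2.43e-05), TUG1 (0.85, SE 0.06, adjusted p = 3.25e-05) and PVT1 (0.77, SE 0.08, adjusted p = 0.00014) rose, and OIP5-AS1 fell by 0.66 on the log2 scale (SE 0.07, adjusted p = 9.64e-05). NEAT1, KCNQ1OT1, MIAT and MALAT1 were the other members that fell. The MIAT call was lost without DMSO replicate 1 (0.163), DMSO replicate 2 (0.128) or OTS964 replicate 2 (0.0967) and with DESeq2 (0.150). The MALAT1 call was lost without DMSO replicate 1 (0.238) or OTS964 replicate 1 (0.106), with relative log expression size factors (0.0564), with TMM over coding genes (0.142), with the CPM filter (0.0653), without a filter (0.269) and with the replicate number as a block (0.0660).

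Whether intron-poor and intron-rich genes moved differently was asked with coding gene classes. Of 2845 genes with 0 to 3 introns, 892 rose and 916 fell, with a median of -0.02 (camera adjusted p = 0.901). Genes with 4 to 7 and with 8 to 14 introns had medians of -0.02 and -0.05 (camera adjusted p = 0.901 for both). Genes in the shortest quartile of gene length (up to 12.9 kb; 3315 genes) held 1242 rises and 825 falls, with a median of 0.12, and those in the longest quartile (from 78.4 kb; 3316 genes) 648 rises and 1429 falls, with a median of -0.22. Both stood apart from all other genes by camera (adjusted p = 0.0413 up and 0.00619 down), and with an estimated correlation neither did (adjusted p = 0.967 and adjusted p = 0.767). The short-gene call was also lost without DMSO replicate 1 (0.05002), without OTS964 replicate 1 (0.155) and with total counts (0.0566). Among 304 single-exon coding genes 104 rose and 69 fell, with a median of 0.13 and adjusted p = 0.0581, which became 0.0378 without DMSO replicate 1 and 0.0397 without OTS964 replicate 1. Among 3128 genes with 15 or more introns 738 rose and 1180 fell, with a median of -0.13 and adjusted p = 0.0995, which became 0.0397 without OTS964 replicate 1. Across 13263 coding genes, Spearman's rho of the log2 fold change was -0.18 with gene length, -0.0744 with intron number and 0.446 with mean expression. The last was 0.291 to 0.347 for single pairs of libraries with expression taken from the DMSO library outside the pair. Genes are not independent replicates, and the sign of a median within a class shifts with the scaling.

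Small RNA genes that lie inside introns of coding genes on the same strand rose more than their hosts, a comparison chosen after seeing the data. Of 651 such genes (snoRNA, scaRNA, miRNA, snRNA, misc_RNA and rRNA pseudogene biotypes), 358 rose and 49 fell, with a median log2 fold change of 1.13, while the median of their hosts was 0.12. The gene lay above its host in 80.5% of pairs, with a median difference of 1.08 (quartiles 0.36 and 1.70). For the 116 snoRNA genes the medians were 1.74 and 0.42, for 147 miRNA genes 0.96 and 0.09, and for 126 snRNA genes, most of them copies, 0.94 and 0.01. The difference was 1.46 for 71 genes in introns under 1 kb and 0.53 for 111 genes in introns over 30 kb. A difference from the host does not depend on the scaling. These genes are short and often at low counts, and reads of unspliced host RNA may count toward them. Other genes inside coding introns on the same strand lay closer to their hosts. Of 398 sense_intronic genes 120 rose and 93 fell, with a median difference of 0.36 and 59.3% above the host, and of 137 TEC genes (to be experimentally checked) 44 rose and 42 fell, with a difference of 0.15 and 54.7% above.

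**Figure D4:**
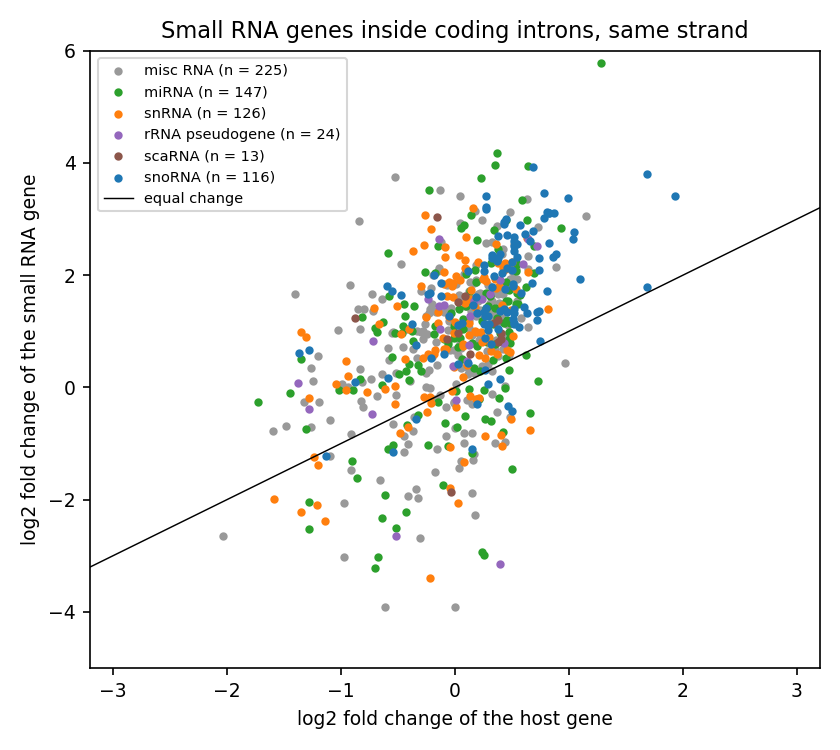
Log2 fold change (OTS964 over DMSO) of small RNA genes inside introns of coding genes on the same strand against that of the host gene, coloured by biotype, with the line of equal change; 3 of the 651 pairs lie outside the plotted range. Points lay above the line in 80.5% of pairs, with medians of 1.13 for the small RNA genes and 0.12 for the hosts.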

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

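Of the settings here, the scaling by mitochondrially encoded mRNAs and the fit without small RNA genes were chosen only after the results were seen, and the rest were planned. Under the mitochondrial scaling SF3B1, PBK and the medians of many lists change sign. Leaving that scaling aside, no called list or class changed the direction of its test. The median of the called elongation list was -0.02 with total counts. Of the called named genes 1 changed direction: H2AC15, at -0.11 and not called with total counts. DDX42 and SNORD3A, which were not called, passed in the opposite direction at -0.28 with total counts and at -0.40 without OTS964 replicate 1 (SNORD3A ranged from -0.40 to 0.91 with 1 library left out). Results that were not called on either side also turned, among them the E2F and S phase, WNT, nuclear lncRNA and cleavage lists and CCNL2. Over all genes, 9 of those called before were called in the opposite direction with total counts, and 2535 under the mitochondrial scaling. The tallies that follow leave out the mitochondrial scaling, the fit without small RNA genes and the test against a 1.5-fold change. For the gene lists 342 values kept their side of the threshold, 31 lost and 11 gained a call. For single named genes 1465 kept it, 95 lost and 5 gained a call. For the kinase and its partners 65 kept it and 1 gained a call. Except where said otherwise, the cause was not tested.

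The number of genes that rose was 2839 with total counts alone, and the numbers that rose and fell were 1373 and 3138 when tested against a 1.5-fold change, which is a stricter question, and 911 and 14927 with the mitochondrially encoded mRNAs set to 0. With 1 library left out, the number that rose ranged from 3659 (without DMSO replicate 1) to 6389 (without OTS964 replicate 1); the lone library of a group was then assumed to vary like the others. As a share of coding counts, mitochondrially encoded mRNAs held 0.913% in DMSO and 1.28% in OTS964, and ribosomal proteins 4.03% and 5.82%; the smaller denominator raises these.

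With an estimated correlation, the adjusted p of lists that camera had called was 0.485 for elongation, 0.525 for G2/M, 0.421 for RNA polymerase III and rRNA, 0.528 for SR proteins and CLK kinases, 0.456 for the U2 snRNP, 0.525 for the activated spliceosome, 0.741 for cholesterol synthesis, 0.456 for colorectal epithelium, 0.421 for heat shock, 0.528 for homologous recombination, 0.528 for hypoxia and glycolysis, 0.421 for immediate early genes, 0.421 for known single-exon genes, 0.456 for mitochondrially encoded mRNAs, 0.421 for replication-independent histones, 0.456 for ribosomal proteins, 0.528 for ribosome biogenesis, 0.456 for snoRNA hosts, 0.358 for snoRNAs and scaRNAs, 0.525 for snRNAs and 0.525 for ZNF genes. It was 0.967 for the shortest and 0.767 for the longest quartile of gene length. Few residual degrees of freedom enter these estimates.

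Cholesterol synthesis lost its call with the CPM filter (adjusted p = 0.0937), with total counts (0.123) and with fry (0.231), and ranged from 0.00451 to 0.251 with 1 library left out. With total counts, hypoxia and glycolysis lost its call (0.0692), and the BCL2 and IAP families (0.0340) and replication-dependent histones (0.0382) gained one. With fry, which does not compare a list with other genes, the BCL2 and IAP families (0.00859) and p53 targets (0.0183) gained a call and snRNAs lost theirs (0.0760). With 1 library left out, the adjusted p ranged from 0.0214 to 0.0648 for the BCL2 and IAP families, 0.00216 to 0.196 for NF-kB targets, 0.000145 to 0.724 for snRNAs, 0.00357 to 0.499 for integrated and ER stress and 0.0210 to 0.100 for hypoxia and glycolysis.

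Single-exon genes gained a call with the CPM filter (adjusted p = 0.0130), without a filter (0.0387) and with total counts (0.0158), and ranged from 0.0378 to 0.0894 with 1 library left out. Genes with the most introns gained one without a filter (0.0328) and with total counts (0.000158), and ranged from 0.0397 to 0.235. With total counts the shortest length quartile lost its call (0.0566) and the next to longest gained one (0.0158); the shortest ranged from 0.0238 to 0.155 with 1 library left out. Spearman's rho with gene length was -0.203 with the CPM filter, -0.141 without a filter and between -0.188 and -0.161 with 1 library left out, and rho with intron number was -0.0549 without a filter and between -0.0847 and -0.0606 with 1 library left out. The log2 fold change of CCNL2 ranged from -0.0177 to 0.281 with 1 library left out.

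The deviations of libraries with the same number from their group means had a correlation of -0.0335 across genes, so no shared deviation was seen. The labels do not say whether the replicate numbers pair the libraries, and this value cannot decide it. With the replicate number as a block 6130 genes rose and 7081 fell, integrated and ER stress (adjusted p = 0.0468) and single-exon genes (0.0345) gained a call, and EGR1 (0.0876), NR4A2 (0.130), NR4A1 (0.0938), DDX5 (0.0562), MALAT1 (0.0660) and RNU4-2 (0.189) lost theirs; it changed no other call of a list or class.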

Other observations

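Of the tests in this part, those of expressed small RNA reads placed in copies, gene length, mitochondrially encoded mRNAs and single libraries, and all comparisons by biotype, intron annotation, snoRNA content and expression quartile, were chosen only after the results were seen.

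Classes of non-coding genes moved in different directions with TMM scaling. Of 2255 processed pseudogenes, which are copies of mRNAs and may take reads of their parent genes, 597 rose and 230 fell, with a median log2 fold change of 0.59. Of 1214 lincRNA genes, 171 rose and 481 fell (median -0.52), and of 1383 antisense genes 197 rose and 465 fell (median -0.33). Of 314 misc_RNA genes, a class that holds copies of 7SL and Y RNA, 150 rose and 31 fell (median 1.01). Antisense counts depend on the strand setting of the counting, which is not given in the sources used here. Of small RNA genes inside coding introns, 32.12% of 2055 on the host's strand passed the count filter and 2.27% of 1191 on the opposite strand. This argues against counting without regard to strand.

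Among abundant genes, those with over 50% of their exon length in retained-intron models alone had higher fold changes than those with none. Genes with a smaller share were not compared. In the highest expression quartile, 146 of 165 genes with over 50% of their exon length in such models alone rose, with a median of 0.52, against 0.29 for 1068 genes with no such length (difference 0.23, permutation adjusted p = 2.5e-05 over 5 comparisons, two-sided). In the lowest quartile the medians were -0.41 and -0.52 (adjusted p = 0.39). These permutations treat genes as independent replicates, which they are not, and expression was matched only by quartile. Among genes with over 30% of such length, NR4A1, an orphan nuclear receptor gene, rose by 3.23 (SE 0.51, adjusted p = 0.0304; lost without DMSO replicate 1, 0.192, or replicate 2, 0.164, without a filter, 0.0616, and with the replicate number as a block, 0.0938), the helicase gene DDX47 by 3.16 (SE 0.08, adjusted p = 9.02e-07), the translation factor gene EIF4A1 by 3.13 (SE 0.12, adjusted p = 8.59e-06) and the mediator gene MED17 by 2.29 (SE 0.08, adjusted p = 2.00e-06), beside CCNL1, RPL21 and RPS26. Coding genes that carry a snoRNA (173 genes) had a median of 0.18, against -0.06 for the other 13090 (permutation p = 0.00012, two-sided). This difference was not seen at like expression: less the median of their class of mean expression (10 classes), the carriers had a median of -0.008 (permutation p = 0.8, labels permuted within classes). Within ribosomal protein genes the medians were 0.87 and 0.73 (n = 11 and 71, p = 0.056). H3C15, a histone gene with a near-identical copy, held 461.8 CPM in DMSO replicate 1 and 14.3, 9.99 and 8.30 CPM in the other libraries. It did not pass the test (-4.70, SE 2.43, adjusted p = 0.24) but did with either DMSO library left out (0.0246 without replicate 1, 0.000472 without replicate 2) and with DESeq2 (0.0198).

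Small RNA genes inside coding introns rose more than their hosts, and a candidate explanation is unspliced host RNA that was read inside introns. The tables argue against a general rise of abundant features, because at matched mean expression the intron genes lay 1.68 above coding genes (medians 1.13 and -0.55, n = 651 each, permutation p = 1e-05, the smallest that the permutations can give). Reads of expressed small RNAs placed in their copies would fall on both strands, but copies on the strand opposite to the host passed the count filter 0.0688 times as often as those on the host's strand (2.43% of 907 against 35.24% of 1084). Unspliced host RNA stays open. The strand difference is what reads of host transcripts inside introns would give, but it concerns which copies had counts, not their change with OTS964. Copies inside coding introns on the host's strand had a median of 0.98 (n = 375). Copies not placed inside an intron of a single coding gene had a median of 0.99 (n = 148). The difference was -0.00433 (95% bootstrap interval -0.26 to 0.19, permutation p = 0.96). It met the bound written beforehand as speaking against unspliced host RNA. A reading by that bound alone was dropped after the value was seen, because the value lay within its own spread. Sense_intronic genes, which such reads could also raise, lay 0.36 above their hosts at the median against 1.08 for the small RNA genes. The reference group of 148 was not strictly outside introns. It could hold copies that touch an exon of a coding gene, or lie within several coding genes or within non-coding genes. Unspliced RNA may count toward such copies too. The group also includes expressed U1, U4 and 7SL genes and copies, which makes it a weak reference. The difference of -0.00433 therefore cannot decide. No effect of the inhibitor on splicing was tested here.

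The log2 fold change rose with mean expression across coding genes, and a candidate explanation is a larger share of RNA made before treatment in the OTS964 nuclei. The tables argue against GC content and gene length as its source: the median rho within 10 classes of GC content was 0.46 (0.32 to 0.51) and within 10 classes of gene length 0.476 (0.44 to 0.50), against 0.446 over all coding genes (0.291 to 0.347 for library pairs with expression from the DMSO library outside the pair). The mitochondrially encoded mRNAs, which RNA polymerase II does not make, lay 0.433 above the highest expression quartile (medians 0.73 and 0.30, n = 13 and 3316), but both medians were known before this test was written, so it lends no support. Cytoplasm or mitochondria carried over in greater amount into both OTS964 preparations would raise the same RNAs and cannot be told apart from it, since it is confounded with the group. Taken as replicate 2 over replicate 1, rho was 0.018 between the DMSO libraries and -0.139 between the OTS964 libraries. The order of the replicates is arbitrary, so only the size of these values can be read, and both were smaller than between groups.

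Immediate early genes rose, and a response to the inhibitor is a candidate explanation that was not itself tested. Their length, intron number and expression account for part of it at most, since the median of the list lay 0.506 above that of 10000 random coding lists matched on these (0.96 against 0.45, with 95% of the random medians between 0.22 and 0.59). Uneven handling of single libraries was examined with all 34 measured members: the larger difference within a group was a median 0.266 of the difference between groups. Since 29 of the 34 had been called as rises, which needs small differences within groups, this value decides nothing. Handling that both OTS964 libraries shared is confounded with the group and cannot be told apart from the inhibitor.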
